A study of Mus musculus with 18 samples.

How the data were processed

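Total RNA was measured by RNA sequencing in 3 bone marrow cell populations of C57BL/6 mice, each sorted by flow cytometry from Ptbp1 fl/fl animals (WT here) and from Ptbp1 knockout animals (KO). Each of the 6 groups holds 3 libraries, which the labels call biological replicates, so that 18 libraries were analysed. Counts of replicates differed by more than sampling noise: the chi-square per degree of freedom of a pair, over genes with at least 20 reads, was 13.6 to 159. Per the labels' protocols, RNA was isolated with a column kit for small samples, amplified into double-stranded cDNA with the NuGEN Ovation RNA-Seq System V2, and made into libraries with the NuGEN Ovation Ultralow System V2. The labels do not say that the libraries keep strand, so reads of overlapping genes on opposite strands are not told apart here.

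The deposited files hold, for each library, the estimated count of reads and the TPM, an abundance corrected for transcript length, of every transcript, in the format that Salmon writes. Salmon version 0.12.0 and the genome builds mm10 and GRCm38.p6 are named per the submitters' processing notes; its index and options are not given in the sources used here. Estimated counts are not whole numbers, because Salmon divides a read that fits several transcripts among them, and 82.9% of those above 0 in a median library were not whole. Genes that share reads with near-identical copies, such as ribosomal protein genes and their processed pseudogenes, therefore carry uncertain values.

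Transcripts were matched by identifier to the GENCODE M21 annotation of GRCm38. Of 136288 transcripts, 136176 matched, 99.2% of them with the same length, and the 112 without a match held at most 0.084% of a library's reads. Estimated counts were summed over the transcripts of a gene, giving 53458 genes, and rounded to whole numbers. Total estimated counts ran from 15956408 to 29226287 per library. Mitochondrial ribosomal RNA took 12.7% to 33.5% of the reads and protein-coding genes 56.1% to 79.5%. Transcripts under 200 bases held 23.0% to 41.1% of a library's TPM but at most 1.14% of its reads. In the main tests TPM was therefore used only for transcripts of single genes, as shares, levels or minimum levels. Levels set across libraries carry that difference. The length-scaled counts, used as an alternative, were built from the TPM of all genes and rescaled to library totals.

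Gene counts were tested with edgeR version 4.0.16 (quasi-likelihood, robust, TMM factors, filterByExpr) in R version 4.3.3. All 18 libraries entered a single fit with 6 group means and 12 residual degrees of freedom, and 21565 genes passed the filter. Adjusted p values are Benjamini-Hochberg values over those genes, called below 0.05. Gene levels are CPM on TMM-scaled library sizes, as mean ± SD over 3 libraries, and fold changes are on the log2 scale with their standard error (SE). The contrasts were KO against WT in each population, the difference of that effect between populations, and WT preMegE against WT HSC and WT preCFU-E against WT preMegE.

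Gene lists were written down from general knowledge: 36 lists with 1148 entries, of which 1144 matched the annotation (Snhg4, Hbb-b1, Hbb-b2 and Ahsp did not). Globins had under 5 members past the filter, so 35 lists were tested. Each was tested with camera in limma version 3.58.1, which compares a list with all other genes at a preset correlation of 0.01 between genes, adjusted over the lists. The same test with the correlation estimated from the data, and fry, were alternatives. The median, mean and test of a list had the same sign for every called list. They differed in sign for some lists without a call: megakaryocyte, heat shock, immediate early and cholesterol genes in HSC, PTB family and apoptosis genes in preMegE, and HSC signature, heme and ribosome biogenesis genes in preCFU-E, B cell, macrophage and PTB family genes between WT preMegE and HSC, and glycolysis genes between WT preCFU-E and preMegE. Several lists share members, and the series' own title names ribosomal constituents, so the ribosomal lists are not independent of what was found in these samples.

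Transcript usage was tested with edgeR's diffSpliceDGE (Simes p per gene) on rounded transcript counts, for transcripts holding at least 5% of their gene's TPM, in 9364 genes. Cassette exons were taken from the annotation as internal exons that some transcripts contain and others skip. Percent spliced in is the TPM of transcripts with the exon over the TPM of transcripts with or without it. It was tested with limma on the logit scale (offset 0.01) for 5210 exons with a mean of at least 5 TPM and a mean percent spliced in from 2 to 98. An exon was called at an adjusted p below 0.05 and a change of at least 10 percentage points. These values rest on Salmon's division of reads among annotated transcripts, not on counted junction reads, and values of exactly 0 or 100 come from that division.

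The tests of genes, lists and usage were tried on simulated counts with 200 changed genes per population, drawn from the means and spreads of these libraries. The exon test was tried on simulated percent spliced in. For changes of 1 and 2 on the log2 scale, the shared fit of all libraries recovered 49% and 81% in preMegE with 4 false calls among 20546 genes, and 50% and 90% in preCFU-E with 5 false calls among 20624. In HSC it recovered 35% and 69% with 156 false calls among 20404, against 8% and 49% with 3 false calls among 19372 when the HSC libraries were fitted alone. Fits of a population's own libraries recovered 58% and 88% in preMegE with 12 false calls among 16296. In preCFU-E they recovered 83% and 96% with 16 among 13729. For the difference between preMegE and HSC effects, with changes placed in preMegE, 17% and 67% were recovered with 19 false calls among 20546. A list of 50 genes lowered by 0.35 was found in each population and 0 of 34 unchanged lists were called. Simulated genes were drawn independently of each other, so this does not show how the list test behaves when genes vary together. Other splits of the real libraries gave up to 9, 18 and 24 called lists in HSC, preMegE and preCFU-E. For transcript usage, 85, 69 and 71 of 200 changed genes were recovered in HSC, preMegE and preCFU-E with 322, 28 and 20 false calls among 8745, 8756 and 8767 genes. For exons, noise with each exon's own spread was added to percent spliced in on the logit scale, and no counts were drawn. Of 200 exons shifted by 30 points, 64, 39 and 47 were recovered with 139, 14 and 5 false calls among 5030, 5024 and 5023 exons.

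The groups, tests, lists, alternatives and naming rule were chosen before the data were examined. In each KO against WT comparison the text names Ptbp1, Ptbp2 and Ptbp3, and the 6 largest rises and falls among called protein-coding genes with a curated symbol, a mean log2 CPM of at least 2 and no overlap between the groups. Of each list described, it names up to 3 called members by smallest p, or the 2 most abundant members where none was called; a comparison with fewer than 5 calls names all with a curated symbol. Where 2 or more parts of the rule name a gene, it is named once. Differences between effects name the 4 smallest p per direction. WT comparisons name the 5 smallest p per direction and the top 3 members of the erythroid, HSC, megakaryocyte and ribosomal lists. Usage and exons name the 8 smallest p per population with Ptbp1, Ptbp2, Ptbp3 and Pkm. Where a gene outside the rule is named, the text says so, and some genes that the rule takes are not reported here.

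The alternatives were RLE factors, DESeq2 version 1.42.0, limma voom with quality weights, no filter, a stricter filter (1 CPM in 3 libraries and a mean of 50 reads), length-scaled counts, protein-coding genes alone, separate fits per comparison, a replicate block, and each library left out in turn. Lists, usage and exons had estimated correlation, fry, limma's diffSplice, a 10% minimum share, a 20 TPM minimum, a change of 20 points and an offset of 0.05. After the data were seen, fits without mitochondrial ribosomal RNA genes, own-population fits of lists, usage, exons and overlaps, and fits without 3 libraries that stand apart were added. Those 3 libraries are HSC KO 2, preMegE KO 1 and preCFU-E KO 3, while HSC WT 2 was kept.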

Results

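The data describe 3 steps of blood cell formation in mouse bone marrow, with and without Ptbp1. PTBP1 is an RNA-binding protein of the PTB family that controls alternative splicing. HSCs are hematopoietic stem cells, sorted as Lin- Sca-1+ c-kit+ CD150+ CD48- cells. PreMegE cells are progenitors of the megakaryocyte and red cell lineages, and preCFU-E cells are their progeny committed to red cells. Each population had 3 WT and 3 KO libraries, with 15956408 to 29226287 estimated reads each. The first principal component of log2 CPM held 64.1% of the variance and ordered the libraries from HSC through preMegE to preCFU-E. Replicates of HSC varied more than those of the other populations: the common biological coefficient of variation was 0.474 in HSC, 0.238 in preMegE and 0.127 in preCFU-E. All 6 HSC libraries had 6430 to 8620 CPM of Xist, the RNA of the inactive X chromosome. The other 12 had at most 1.09 CPM of Xist and 38.3 to 85.2 CPM of the Y-linked gene Eif2s3y. HSC thus differ from both progenitor populations in the sex genes as well as in cell type, and these cannot be told apart between populations. WT and KO libraries of a population matched in these genes. Of single libraries, HSC KO 2 lay at -138.9 on the third component, where the other 17 lay between -17.1 and 42.3, and preMegE KO 1 lay at 75.4 and HSC WT 2 at -62.2 on the fourth, where the others lay between -25.2 and 40.0. PreCFU-E KO 3 had 12.7% mitochondrial ribosomal RNA, against 28.8% and 27.0% in KO 1 and KO 2.

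The targeted gene was examined first, to see what the knockout left of it. Ptbp1 (ENSMUSG00000006498, GRCm38 chromosome 10, 79854427 to 79864771) fell in the KO libraries of every population, from 208 ± 12.5 to 98.1 ± 8.83 CPM in HSC, from 693 ± 95.8 to 203 ± 25.4 in preMegE and from 1240 ± 117 to 306 ± 10.5 in preCFU-E (SD, n = 3). The log2 changes were -1.09 (SE 0.13), -1.77 (SE 0.13) and -2.02 (SE 0.13), with edgeR adjusted p of 0.000211, 1.2e-07 and 5.51e-09. The reads left in KO libraries lay mostly in transcripts annotated as retaining introns: Ptbp1-205 held 32.9, 52.4 and 61.8 TPM in the KO populations, and Ptbp1-213 held 31, 24.5 and 20.5 TPM against 8.22, 0.355 and 0.799 in WT. The protein-coding transcripts together fell to 3.29%, 9.65% and 6.48% of their WT TPM in HSC, preMegE and preCFU-E. Ptbp1-203 and Ptbp1-214 were at 0 TPM in the KO mean of each population and at 13.5 to 203 TPM in WT. The paralog Ptbp2 (ENSMUSG00000028134, chromosome 3, 119718742 to 119784466), best known from neurons, rose from 56 ± 10.3 to 115 ± 19.5 CPM in HSC, from 17.8 ± 2.04 to 82.7 ± 7.42 in preMegE and from 10 ± 2.01 to 139 ± 7.9 in preCFU-E. Its log2 changes were 1.04 (SE 0.17), 2.22 (SE 0.18) and 3.78 (SE 0.19), with edgeR adjusted p of 0.00583, 3.45e-07 and 8.68e-11. Ptbp3, the remaining family member, had log2 changes of -0.08, -0.05 and -0.04 with adjusted p of 0.86, 1 and 1 in edgeR. The HSC call of Ptbp2 was lost when the HSC libraries were fitted alone (adjusted p 0.466).

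**Figure D1:**
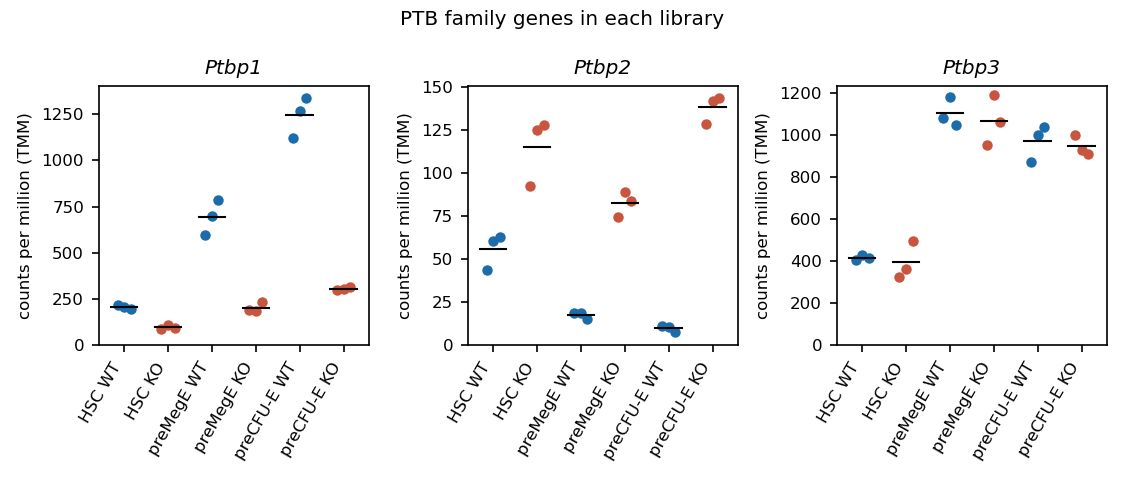
CPM (TMM-scaled, vertical axis, starting at 0) of Ptbp1, Ptbp2 and Ptbp3 in each of the 18 libraries, by group (horizontal axis). Points are libraries (blue WT, red KO) and black lines are group means; the KO points of Ptbp1 lie below, and those of Ptbp2 above, the WT points in each population, with means of 306 against 1240 and 139 against 10 in preCFU-E.

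In HSC, loss of Ptbp1 was accompanied by higher Tmem86b, which encodes a lysoplasmalogenase, at 24.6 ± 3.44 against 5.01 ± 1.01 CPM (log2 2.29, SE 0.23, adjusted p 2.94e-05). Vldlr, a lipoprotein receptor, was at 72 ± 10.6 against 23.5 ± 3.24 CPM (log2 1.61, SE 0.23, adjusted p 0.00165). The sialomucin gene Podxl (log2 1.73, SE 0.40), Sdsl (1.49, SE 0.26), Nagpa (1.33, SE 0.27) and Snapc2 (1.24, SE 0.29) also rose, with adjusted p of 0.0411, 0.00983, 0.0284 and 0.0411. Among called genes with a mean log2 CPM of at least 2 and no overlap between WT and KO libraries, the largest falls were those of Wdr78 (-1.98, SE 0.36), the protease gene Ctse (-1.79, SE 0.31), the deubiquitinase gene Otud1 (-1.68, SE 0.32), the histone gene Hist1h4c (-1.65, SE 0.31), Abhd14b (-1.63, SE 0.36) and the endosomal GTPase gene Rab4a (-1.60, SE 0.26), with adjusted p from 0.00459 to 0.037. In all, edgeR called 182 of 21565 genes, 83 higher and 99 lower. That number depends on sharing an estimate of spread with the less variable progenitors. Fitting the 6 HSC libraries alone called 5 genes, and the simulation of the shared fit gave 156 false calls in HSC. The fit of HSC libraries alone also recovered fewer simulated changes (8% and 49% against 35% and 69%), so lost power may add to its lower count. Ptbp1, Tmem86b and Vldlr passed in each of 11 analysis settings and in each of the 6 fits without 1 HSC library. The HSC count was 89 without WT 2, 395 without KO 1 and 595 without KO 3. The calls of Sdsl, Wdr78, Otud1, Hist1h4c, Rab4a, Ctse, Nagpa, Snapc2, Podxl and Abhd14b were each lost in the fit of HSC libraries alone, with adjusted p up to 0.777. Single libraries ended the calls of Otud1 and Hist1h4c (without WT 2; adjusted p 0.0578 and 0.0514), Nagpa and Abhd14b (without WT 2 or WT 3; up to 0.0764 and 0.0968), Snapc2 (without any WT library or KO 2; up to 0.133) and Podxl (without any library but KO 2; up to 0.12).

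Among the gene lists in HSC, replication-dependent histone genes, whose products package newly made DNA, stood lower in KO. Their median log2 change was -0.63 and 38 of 40 members were negative (camera adjusted p 1.69e-13; adjusted p = 0.615 with an estimated correlation). Their medians were -0.59, -0.95 and -0.58 in KO 1, KO 2 and KO 3, against -0.11 to 0.09 in the WT libraries. EdgeR called 2 members over all genes, Hist1h4c and Hist1h2bb (log2 -1.37, SE 0.31, adjusted p 0.0379), and 14 when adjusted over the list alone. The call of Hist1h4c was lost without WT 2 (0.0514) and that of Hist1h2bb without WT 3 or KO 2 (up to 0.165). Genes of the G2 and M phases of the cell cycle were lower as a list (median -0.30, adjusted p 1.23e-05; adjusted p = 0.975 with an estimated correlation), with medians of -0.43, -0.64 and 0.11 in KO 1, KO 2 and KO 3 and of 0.20, 0.10 and -0.23 in the WT libraries. Mki67 was at 559 ± 307 against 606 ± 33 CPM and Top2a at 276 ± 95.5 against 309 ± 47.9. The Mki67 difference passed only without KO 3 (log2 -0.67, adjusted p 0.0305). Of their 54 members edgeR called 0 over all genes, with 12 lower and 1 higher at an unadjusted p under 0.05, DESeq2 called 2 and voom 0, and 1 fell when adjusted over the list alone. Erythroid markers were lower (median -0.46, adjusted p 7.63e-05; adjusted p = 0.975 with an estimated correlation), with medians of -0.15, -0.84 and -0.23 in KO 1, KO 2 and KO 3 and of -0.08, -0.13 and 0.31 in WT 1, WT 2 and WT 3. WT 3 also had the highest medians of granulocyte and monocyte markers (1.01) and of endothelial and stromal markers (0.60) among the HSC libraries, and 18.1 CPM of Car1 against 2.51 and 1.61 in WT 1 and WT 2. Of these 40 genes 2 fell over all genes, the water channel gene Aqp1 (log2 -1.07, SE 0.21, adjusted p 0.0202) and Add2 (adjusted p 0.00795), which had 4 to 8 reads in WT libraries and 0 in KO. Aqp1 was lost without WT 2 or WT 3 (up to 0.0595). Adjusted over the list alone, 10 fell and 2 rose. Ribosome biogenesis factors were higher (median 0.12, adjusted p 0.0328; adjusted p = 0.975 with an estimated correlation), with Npm1 at 860 ± 206 against 851 ± 115 CPM and Ncl at 813 ± 208 against 730 ± 72.4, and 2 members rose when adjusted over the list alone. EdgeR called 0 of these factors over all genes, with 9 higher and 1 lower at an unadjusted p under 0.05, where DESeq2 called 3 and voom 0. Library HSC KO 2, which stood apart from the rest, had medians of -0.95 for histones, -0.64 for G2 and M genes and -0.84 for erythroid markers, and without it the G2 and M list had an adjusted p of 0.0669. The ribosome biogenesis call was lost without WT 1, KO 1 or KO 3 (adjusted p up to 0.683) and with HSC libraries alone (0.0528).

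Ribosomal protein genes as a list did not pass in HSC: the 47 large-subunit genes had a median of 0.11 (camera adjusted p 0.0823) and the 32 small-subunit genes 0.06 (0.542). Rpl4 was at 842 ± 47.3 against 789 ± 70.8 CPM and Rps6 at 453 ± 55.9 against 438 ± 29.8. EdgeR called 0 members of either list, with 6 and 1 at an unadjusted p under 0.05, while DESeq2 called 1 of each and voom 0; adjusted over the list alone 1 small-subunit gene rose. The HSC signature had a median of -0.01 (camera adjusted p 0.671), with Hlf at 497 ± 81.1 against 614 ± 3.09 CPM. Of single list members, the mitochondrial ribosomal protein gene Mrps18b fell (log2 -1.96, SE 0.31), as did the heme synthesis gene Alas1 (-1.14, SE 0.26) and the transporter gene Abcg2 (-0.59, SE 0.14). Of the p53 targets Phlda3 rose, at 0.752 to 1.97 CPM in KO against 0 to 0.151 in WT (3.77, SE 0.66). Dcxr fell, at 0.318 to 0.619 CPM in KO against 0.709 to 2.57 in WT (-1.83, SE 0.44). The stromal chemokine gene Cxcl12 fell, at 0.0884 to 0.636 CPM in KO against 1.61 to 9.27 in WT (-3.98, SE 0.86). EdgeR adjusted p for these 6 ran from 0.00459 to 0.0474, and each was lost in the fit of HSC libraries alone (0.583 to 0.797). Mrps18b and Phlda3 passed with any single library left out, but the fitted fold of Phlda3 starts from a WT level near 0. The others were lost: Alas1 without WT 1, WT 2 or KO 2 (up to 0.136), Abcg2 without any but KO 3 (up to 0.13), Dcxr without WT 1, WT 3, KO 1 or KO 2 (up to 0.16) and Cxcl12 without WT 3 or KO 2 (up to 0.139). With RLE factors Dcxr and Abcg2 were lost too. Lists of other blood, immune and endothelial cell types did not pass in HSC, and all lists without a call there had camera adjusted p from 0.0823 to 0.977.

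In preMegE, the named changes beside Ptbp1 and Ptbp2 were those of 8 genes, of which Atat1, Tmem86b, Necap2, Mlkl, Dnmt3b and Pgm2 were also called in another population. Atat1, the tubulin acetyltransferase gene, was at 21.2 ± 2.45 against 5.96 ± 1.94 CPM (log2 1.83, SE 0.28), B4galt6 at 7.12 ± 1.44 against 2.27 ± 0.446 (1.64, SE 0.30), Tmem86b at 19.9 ± 3.76 against 8.61 ± 1.2 (1.21, SE 0.22) and the phosphodiesterase gene Pde3b at 29.4 ± 4.92 against 12.9 ± 1.41 (1.19, SE 0.21). Necap2, an endocytosis factor gene, fell from 54.4 ± 3.62 to 17.3 ± 3.01 CPM (-1.65, SE 0.19), Mlkl, the effector of necroptosis, from 20.9 ± 2.17 to 6.66 ± 0.944 (-1.65, SE 0.24), the DNA methyltransferase gene Dnmt3b from 88.2 ± 16.6 to 30.8 ± 4.09 (-1.51, SE 0.20) and the phosphoglucomutase gene Pgm2 from 74.2 ± 8.71 to 36.6 ± 3.2 (-1.02, SE 0.17). EdgeR called 13 genes, 8 higher and 5 lower, with adjusted p from 0.000146 to 0.0405 for these 8. The count fell to 4 without WT 2, to 8 without WT 1, WT 3, KO 2 or KO 3, and was 36 with preMegE libraries alone. In simulation the fit of preMegE libraries alone recovered more changes (58% and 88% against 49% and 81%), with 12 false calls against 4. Ptbp1, Ptbp2 and Necap2 passed in every setting run and every fit without 1 library, and Dnmt3b in every such fit but not with length-scaled counts (adjusted p 0.343). Those counts also ended the calls of Atat1 (0.64), Tmem86b (0.137), Pgm2 (0.137), B4galt6 (0.103) and Mlkl (0.0805). B4galt6, Tmem86b and Pde3b passed in none of the 6 fits without 1 library (up to 0.391, 0.391 and 0.26). Atat1 was lost without WT 2 or WT 3 (up to 0.0859), Mlkl without WT 2 or KO 3 (up to 0.0609) and Pgm2 without any library but WT 1 (up to 0.123).

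Lists of cell division genes stood lower in KO preMegE at the preset correlation. The S phase list had a median of -0.35 with 47 of 48 members negative (camera adjusted p 1.58e-15), and the G2 and M list a median of -0.26 with 50 of 54 negative (7.6e-10), but with an estimated correlation they had adjusted p = 0.328 and 0.48. EdgeR called 0 members over all genes in either list, with 10 and 7 lower at an unadjusted p under 0.05. DESeq2 called 1 and 0 and voom 3 and 6, and 1 S phase gene fell when adjusted over the list alone. Mcm6, part of the replicative helicase, was at 346 ± 71.7 against 408 ± 87.3 CPM and Top2a at 474 ± 90 against 589 ± 49.8. The more abundant Mki67 was less clear, at 928, 870 and 573 CPM in KO 1, KO 2 and KO 3 against 851, 876 and 787 in WT. S phase medians were -0.37, -0.18 and -0.41 in the KO libraries and -0.25, 0.02 and 0.24 in the WT libraries. G2 and M medians were 0.01, -0.29 and -0.54 in KO 1, KO 2 and KO 3 and -0.13, 0.01 and 0.12 in WT. Cytosolic tRNA synthetases (median -0.26, adjusted p 3.35e-06), ribosome biogenesis factors (-0.17, 5.81e-06), glycolysis genes (-0.26, 0.000248), heme and iron genes (-0.19, 0.00139), splicing factors of the hnRNP and SR families (-0.11, 0.00177), macrophage and dendritic cell markers (-0.37, 0.0045), cholesterol synthesis genes (-0.20, 0.00467), megakaryocyte markers (-0.25, 0.00568) and erythroid markers (-0.15, 0.0435) were lower as lists at the preset correlation. These 9 lists had adjusted p = 0.328 to 0.549 with an estimated correlation. Eprs was at 240 ± 39.6 against 296 ± 28.8 CPM, Gapdh at 694 ± 105 against 902 ± 127 and Apoe at 158 ± 52.9 against 272 ± 55.6. Large-subunit ribosomal protein genes were higher (median 0.11, adjusted p 0.000643), as were small-subunit genes (0.13, 0.000785; adjusted p = 0.487 for both with an estimated correlation), with Rpl10 at 1860 ± 354 against 1650 ± 199 CPM and Rps4x at 2350 ± 393 against 1970 ± 230. EdgeR called 0 ribosomal protein genes, also when adjusted over the list alone, with 1 of each subunit at an unadjusted p under 0.05, and DESeq2 and voom called 0. P53 targets (median 0.16, adjusted p 0.00541), granulocyte and monocyte markers (0.70, 0.0321) and mitochondrially encoded genes (0.52, 0.000544) were also higher, with adjusted p = 0.328, 0.487 and 0.487 with an estimated correlation. Over all genes edgeR called 0 members of these other 12 lists, with 0 to 7 members of a list at an unadjusted p under 0.05, where DESeq2 called at most 1 and voom at most 4. Adjusted over the list alone, 1 tRNA synthetase, 1 heme and iron gene, 1 erythroid marker, 1 macrophage marker and 2 splicing factors fell. Both ribosomal calls were lost without KO 3 (adjusted p up to 0.238 and 0.165), whose medians were 0.22 and 0.23, and the large-subunit call also without WT 1. Other calls were lost without WT 1 (p53 targets and macrophage markers, 0.0855 for the latter), WT 2 (cholesterol synthesis, 0.0551), WT 3 (glycolysis, 0.0533; hnRNP and SR factors, and these also without KO 1, up to 0.186; erythroid markers, and these also without KO 2, up to 0.618), KO 2 (megakaryocyte markers, 0.0978; p53 targets) or KO 3 (granulocyte markers, 0.112; p53 targets, up to 0.137). Erythroid markers had a mean of -0.03. Mitochondrially encoded genes moved with single libraries: their medians were 1.05 in WT 1 and -0.45 and -0.59 in the other WT libraries, and 1.05, 0.80 and 0.21 in KO.

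In preCFU-E, Ptbp2 rose most of the named genes, and the sialomucin gene Podxl was at 13.4 ± 2.52 against 2.63 ± 0.486 CPM (log2 2.36, SE 0.43). Atat1 (1.88, SE 0.29), the myosin phosphatase subunit gene Ppp1r12b (44 ± 3.9 against 15.9 ± 0.587 CPM; 1.47, SE 0.20), Mdga1 (1.41, SE 0.23) and Tmem86b (1.38, SE 0.22) rose. The GABA-B receptor gene Gabbr1, a known PTBP1 splicing target, rose from 0.277 ± 0.13 to 1.92 ± 0.603 CPM (2.84, SE 0.39). Abhd14b fell from 11.8 ± 2.07 to 2.4 ± 0.301 CPM (-2.30, SE 0.38), Pgm2 from 121 ± 18.2 to 38.5 ± 4.43 (-1.65, SE 0.17), the DNA repair gene Uvssa from 16.9 ± 0.837 to 5.77 ± 0.944 (-1.55, SE 0.22), Mlkl from 16.3 ± 4.71 to 5.64 ± 0.955 (-1.53, SE 0.25) and Dnmt3b from 86 ± 10.2 to 30.3 ± 3.85 (-1.50, SE 0.20). EdgeR called 33 genes, 17 higher and 16 lower, with adjusted p from 3.22e-05 to 0.0146 for these 11 genes. The count was 14 without WT 2, 21 without KO 3 and 252 with preCFU-E libraries alone. The common biological coefficient of variation was 0.354 in the shared fit and 0.127 in preCFU-E. In simulation the fit of preCFU-E libraries alone recovered more changes (83% and 96% against 50% and 90%), with 16 false calls against 5. The shared fit may thus miss changes in preCFU-E. Ptbp1, Ptbp2, Pgm2, Uvssa and Dnmt3b passed in every setting run and every fit without 1 library. With length-scaled counts the calls of Ppp1r12b, Gabbr1, Atat1, Podxl, Mdga1 and Tmem86b were lost (adjusted p 1, 0.414, 0.32, 0.233, 0.161 and 0.0515). Single libraries ended the calls of Podxl (all but KO 2; up to 0.173), Atat1 (WT 2; 0.0576), Mdga1 (WT 2, WT 3 or KO 2; up to 0.113), Tmem86b (WT 2, WT 3 or KO 3; up to 0.074), Abhd14b (WT 2, KO 1 or KO 2; up to 0.0633) and Mlkl (WT 2 or KO 3; up to 0.0634).

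Of the lists in preCFU-E, macrophage and dendritic cell markers stood lower (median -0.59, 15 of 17 negative, camera adjusted p 0.000657; adjusted p = 0.0975 with an estimated correlation), with medians of -0.67, -0.40 and -0.67 in the KO libraries. The iron exporter gene Slc40a1 was at 77.6 ± 5.21 against 99.9 ± 10.8 CPM, and 1 member fell when adjusted over the list alone. The more abundant marker Ctsb went the other way, at 127, 130 and 149 CPM in KO 1, KO 2 and KO 3 against 109, 127 and 139 in WT. EdgeR called 0 members over all genes, with 4 lower at an unadjusted p under 0.05, DESeq2 1 and voom 2, of which Slc40a1 was 1 (adjusted p 0.0229). The snoRNA host genes were lower with 0 of 14 positive (median -0.27, adjusted p 0.00293; adjusted p = 0.632 with an estimated correlation), a call lost without WT 1 (0.526), with Gas5 at 141 ± 2.28 against 207 ± 87 CPM. The other 13 lists were higher, among them nuclear genes of oxidative phosphorylation (median 0.12, 55 of 61 positive, 0.000657; 0.0608 without KO 2), glycolysis (0.18, 0.00101; 0.118 without WT 1), p53 targets (0.21, 28 of 35 positive, 0.00173), interferon response genes (0.30, 0.00173; 0.588 without KO 1) and immediate early genes (0.34, 17 of 20 positive, 0.0029), of which Egr1 was at 25.7 ± 10.4 against 12 ± 1.08 CPM. With an estimated correlation these 5 lists had adjusted p = 0.632, 0.632, 0.139, 0.632 and 0.113 in that order. EdgeR called 0 immediate early genes over all genes, with 1 at an unadjusted p under 0.05, DESeq2 called 1 (Egr1) and voom 0, and adjusted over the list alone 1 of these and 1 glycolysis gene rose. Endoplasmic reticulum chaperones (0.14, 0.00536), cytosolic heat shock proteins (0.16, 0.00579), mitochondrial ribosomal proteins (0.09, 0.0244), translation factors (0.06, 0.0427) and ATF4 targets (0.15, 0.0427) were higher, and these 5 were each lost without WT 1, KO 2 or KO 3 (up to 0.846, 0.756, 0.526, 0.756 and 0.533), with translation factors pointing down without WT 1. With an estimated correlation they had adjusted p = 0.632 to 0.9. Without KO 2, 7 lists were called. Large-subunit ribosomal protein genes had a median of 0.07 (0.00434) and small-subunit genes 0.05 (0.0427), with adjusted p = 0.715 and 0.843 with an estimated correlation. EdgeR called 0 ribosomal protein genes, also when adjusted over the list alone, with 1 of each subunit at an unadjusted p under 0.05, where DESeq2 called 0 and voom 1 large-subunit gene. The 11 other lists had 0 members called in edgeR, 0 to 4 at an unadjusted p under 0.05, 0 called in DESeq2 and at most 1 in voom. Both ribosomal calls were lost without WT 3 or KO 2 and in the fit of preCFU-E libraries alone, and the small-subunit call also without KO 3 (up to 0.956 and 0.624); without WT 3 the small-subunit list pointed down. Mitochondrially encoded genes were higher (median 0.63, 0.000699; adjusted p = 0.636 with an estimated correlation), with KO medians of 0.98, 1.05 and -0.61 in KO 1, KO 2 and KO 3, the library with less mitochondrial ribosomal RNA, and the call was lost without WT 2, KO 1 or KO 2 (up to 0.114). Erythroid markers had a median of -0.02 (camera adjusted p 0.842), with Car1 at 5200 ± 61.9 against 5040 ± 652 CPM, and S phase genes 0.03 (0.666), with Rrm1 at 539 ± 27 against 511 ± 53.1.

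**Figure D2:**
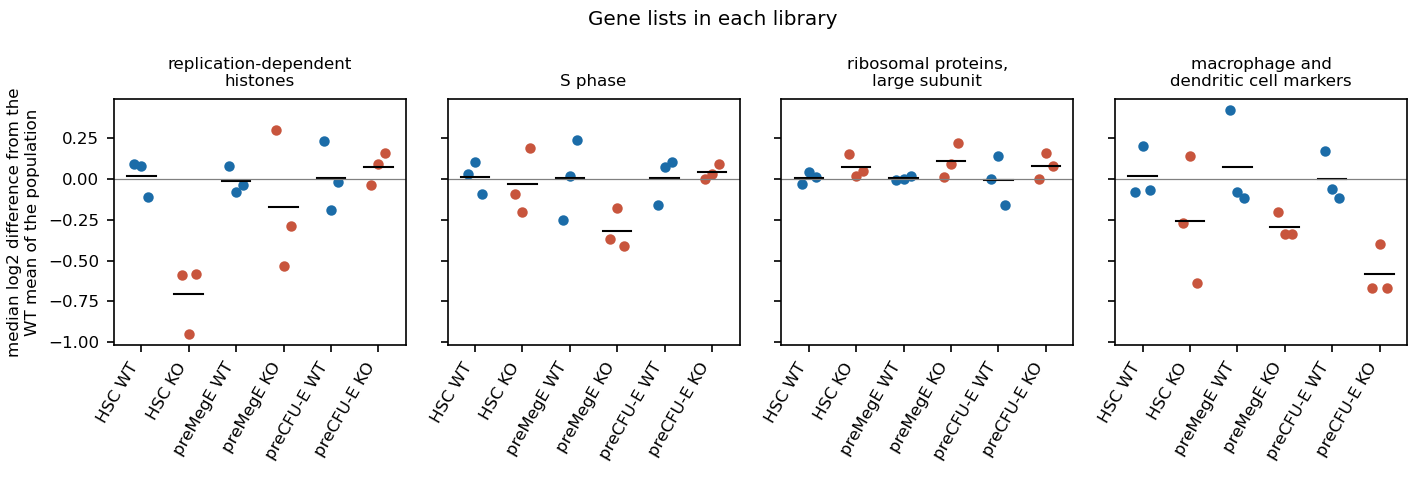
Median log2 difference of 4 gene lists from the WT mean of the same population (vertical axis) in each library (points, blue WT, red KO), by group (horizontal axis), with group means as black lines. Histone medians of the HSC KO libraries lie at -0.59, -0.95 and -0.58, and macrophage and dendritic cell marker medians of the preCFU-E KO libraries at -0.67, -0.40 and -0.67.

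The calls of different populations overlapped, in populations that share no control library. The labels do not say whether the same animals gave several populations, so the populations may not be independent of each other. Ptbp2 and Tmem86b were higher, and Ptbp1 and Mlkl lower, in all 3 populations. PreMegE and preCFU-E shared 4 higher genes (Atat1, Nlrp5-ps, Ptbp2 and Tmem86b) where independent lists would share 0.00631, and 5 lower genes (Dnmt3b, Mlkl, Necap2, Pgm2 and Ptbp1) against 0.00371. HSC and preCFU-E shared 4 higher (Podxl, Ppp1r12b, Ptbp2 and Tmem86b; 0.0654) and 4 lower (Abhd14b, Mlkl, Ptbp1 and Uvssa; 0.0735), and HSC and preMegE 2 higher (0.0308) and 2 lower (0.023). Nlrp5-ps, a pseudogene, was named after its values were seen. One-sided Fisher exact tests across genes gave 1.12e-16 to 0.000404. The lower genes shared by each pair include Ptbp1, the targeted gene, whose fall the design fixed, and no test was run without it. With fits of single populations preMegE and preCFU-E shared 23 genes, HSC and preMegE 2, and HSC and preCFU-E 2. Across 6955 well-expressed genes, which are not independent replicates, fold changes of preMegE and preCFU-E had a Pearson correlation of 0.39, and those of HSC 0.09 with preMegE and 0.08 with preCFU-E. Over all 21565 genes tested the correlations were 0.04, 0.07 and 0.04 in that order. Same-numbered libraries of preMegE and preCFU-E correlated best with their own number in 3 of 3, in WT and in KO. Variation shared by such libraries could raise the correlation and the overlap of these populations, which was not tested.

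Cassette exons were called in KO against WT in each population. A 66-nt exon of the annexin gene Anxa7 (chromosome 14, 20467458 to 20467523) went from 1.93% ± 2.43 to 32.8% ± 17.1 spliced in (SD, n = 3) in preMegE and from 1.3% ± 0.789 to 65.2% ± 3.74 in preCFU-E (limma adjusted p 0.00819 and 0.000145). In preCFU-E an 81-nt exon of Reep6 (chromosome 10, 80334713 to 80334793) went from 3.07% ± 1.68 to 86.9% ± 5.89 and an 18-nt exon of the catenin gene Ctnnd1 (chromosome 2, 84612532 to 84612549) from 4.65% ± 0.389 to 57% ± 3.35 (limma adjusted p 0.000439 each). In preMegE a 24-nt exon of the methionyl-tRNA synthetase gene Mars (chromosome 10, 127296717 to 127296740) went from 0.684% ± 0.184 to 48.5% ± 12.4 and a 20-nt exon of the ribosomal protein gene Rps24 (chromosome 14, 24495430 to 24495449) from 56.1% ± 4.97 to 88.5% ± 2.38. The Rps24 value compares Rps24-202 and Rps24-207 with Rps24-210 and leaves out Rps24-201, which held 93.4% of the gene's TPM in KO and 94.6% in WT preCFU-E. A 58-nt exon of Arih1 (chromosome 9, 59403368 to 59403425) went from 82.6% ± 3.39 to 100%, a 45-nt exon of Araf from 18.3% ± 1.05 to 0% and a 142-nt exon of Tceanc2 from 65.3% ± 14.2 to 100% there. Exons of Meis1 (80.6% to 100%), Dennd1c (77% to 100%) and Smarca2 (100% to 0%) were also called in preCFU-E in the fit of all libraries. These exons could not be tested with preCFU-E libraries alone, where they lay under the minimum of 5 TPM, so their values rest on low levels. A 34-nt exon of Ptbp2 (chromosome 3, 119724612 to 119724645), the exon whose skipping PTBP1 is known to promote, went from 68.6% ± 9.6 to 97.2% ± 3.31 in preCFU-E (limma adjusted p 0.0241). It was at 68.3% ± 6.87 and 91.2% ± 7.47 in preMegE (0.537) and at 69.3% ± 8.28 and 76.3% ± 7.84 in HSC (0.795). In Ptbp1 itself a 34-nt exon (chromosome 10, 79862014 to 79862047) went from 75.4% to 99.2% in preMegE and from 77.6% to 99.8% in preCFU-E. Of the KO transcripts with this exon, the intron-retaining Ptbp1-205 held the most, at 52.4 and 61.8 TPM. As Ptbp1 is the targeted gene, these values may reflect where Salmon placed its remaining reads. Exons of Ptbp3 were not called. Single libraries ended the preMegE calls of Anxa7 (WT 1 or WT 3; adjusted p up to 0.0604), Arih1 (WT 1; 0.054), Rps24 (WT 1, WT 2 or KO 2; up to 0.0627) and Mars (WT 1, WT 3, KO 1 or KO 2; up to 0.0778) and the preCFU-E call of the Ptbp2 exon (any but KO 1; up to 0.13). With a population's own libraries Anxa7 (0.15) and Rps24 (0.0836) in preMegE and the Ptbp2 exon in preCFU-E (0.0887) were lost, and without the 3 libraries that stand apart Mars and the Ptbp2 exon (0.0617) were. A minimum of 20 points removed Araf, Arih1 and Meis1.

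Limma called 114 of 5210 exons in HSC, 13 in preMegE and 31 in preCFU-E, where the simulations gave 139, 14 and 5 false exon calls. The highest exon counts in other splits of the real libraries were 75, 2 and 5, so the simulated numbers do not match the real libraries in HSC and preMegE. Of the called exons in preCFU-E, 23 were more and 8 less included in KO (two-sided exact binomial p 0.0107, and without the Ptbp1 exons 20 and 8, p 0.0357). In preMegE these were 11 and 2 (binomial p 0.0225, and without Ptbp1 9 and 2, p 0.0654). In HSC they were 63 and 51 (binomial p 0.303, and without Ptbp1 61 and 51, p 0.395). The binomial tests treat exons as independent, but the called exons lay in 107, 12 and 27 genes in HSC, preMegE and preCFU-E. Linked exons of a gene can thus count more than once, and these p values do not measure variation between animals. PreMegE and preCFU-E shared 10 called exons where independent sets would share 0.0774, HSC and preCFU-E 10 against 0.678, and HSC and preMegE 7 against 0.284, all in the same direction. Each of these overlaps includes exons of Ptbp1, the targeted gene, whose sharing the knockout itself may fix. Most of the shared exons of each pair lay in other genes, but no overlap was computed without those of Ptbp1. Exons of Anxa7, Ptbp1, Reep6 and Tmem184b were among those called in all populations, and Reep6 outside preCFU-E and Tmem184b outside HSC are named after their values were seen. The Reep6 call was lost in HSC without WT 2 or WT 3 (adjusted p up to 0.0642) or KO 2 (5.64 points, under the minimum of 10) and in preMegE without any 1 library (up to 0.153), and the Tmem184b call in preMegE without any but WT 2 (up to 0.241) and in preCFU-E without any but KO 3 (up to 0.205). Reep6 in HSC was also lost at an offset of 0.05, with own libraries (0.793) and without the 3 libraries that stand apart, and Tmem184b in preMegE in these settings and at 20 points, and in preCFU-E at that offset and at 20 points. With own libraries the HSC calls of Anxa7 (0.31) and of the 31-nt Ptbp1 exon were lost, and both missed a minimum of 20 points there. A 31-nt exon of Ptbp1 missed the minimum of 10 points in HSC without WT 1 or WT 2 (9.22 points without WT 2), and the Anxa7 call was lost in preMegE without WT 1 or WT 3 (up to 0.0604). Of the 8 exons with the smallest p in HSC, those of Ctsa (34.4% to 0%), Gdap2 (76.2% to 0%) and Gtf2i (99.3% to 74%) were lower in KO and those of Pex2, Tmem184b, Abi1, Zmym3 and Pdia4 higher, and each passed in the fits without 1 HSC library. With HSC libraries alone those of Ctsa, Tmem184b, Abi1, Zmym3, Gtf2i and Pdia4 were lost (adjusted p 0.118 to 0.314). In that fit the Gdap2 exon passed (limma adjusted p 0.0295). The Pex2 exon was not tested in it, as it lay under the minimum of 5 TPM in HSC. Only 4 HSC exons were called when HSC libraries were fitted alone. The HSC count was 175 without KO 1 and 228 without KO 3, and the preCFU-E count was 70 with preCFU-E libraries alone. PreMegE gave 4 exons without WT 1, 6 without WT 3 and 7 without KO 1 or KO 2. PreCFU-E gave 11 without WT 1, and 20, 16 and 18 without KO 1, KO 2 and KO 3.

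**Figure D3:**
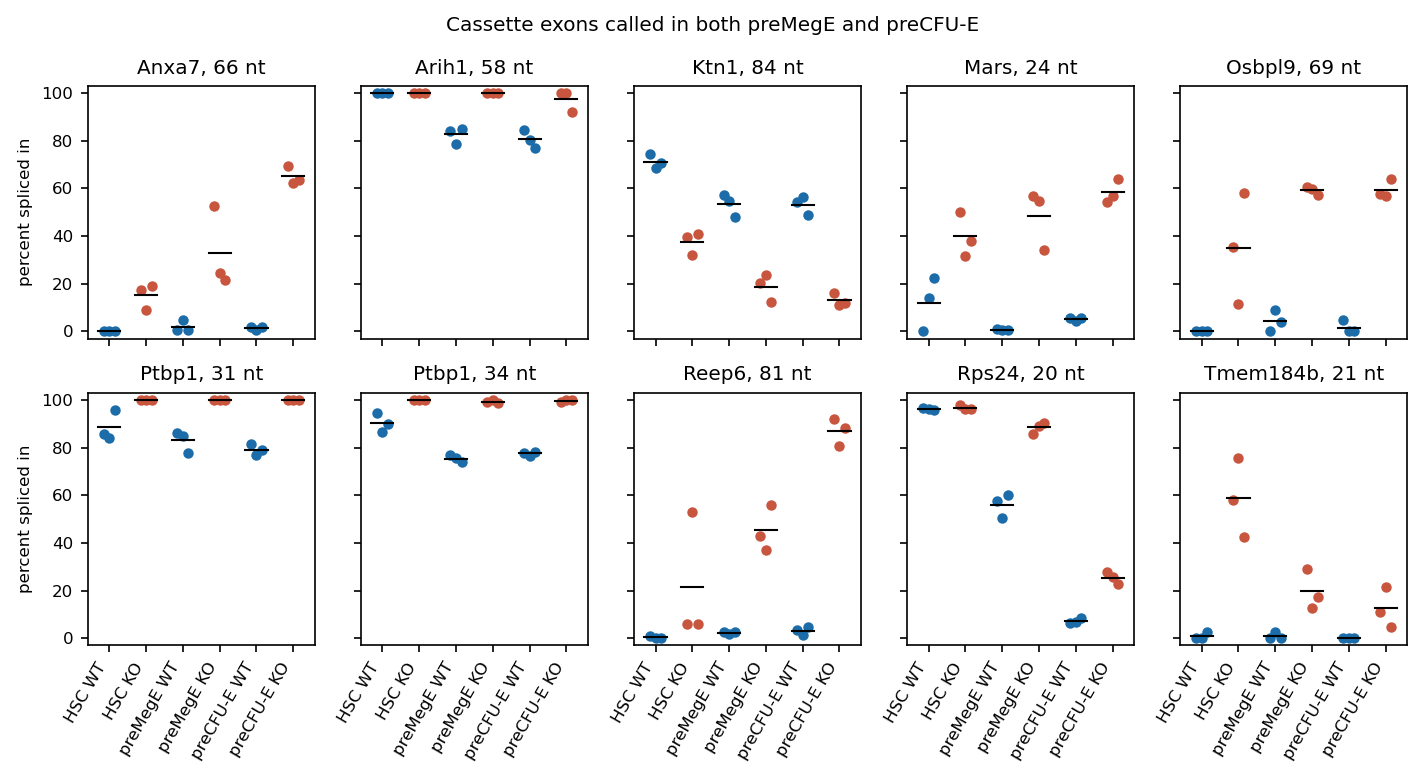
Percent spliced in (vertical axis, 0 to 100) of the 10 cassette exons called in both preMegE and preCFU-E, in each library (points, blue WT, red KO) by group (horizontal axis), with group means as black lines. Each panel names the gene and the exon length in nucleotides; the Reep6 exon lies at 80.5 to 92.1 in the preCFU-E KO libraries and at 1.3 to 4.64 in WT.

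Transcript usage within genes was tested as well. In preMegE the calls were led by Ptbp1, the reticulon gene Rtn4, Anxa7, Sun1, Abi1, Ktn1, Utp6 and Mars. Rtn4-203 held 66% ± 27.2 of its gene's TPM in KO against 17.2% ± 5.32 in WT, and Anxa7-201 0% against 47.3% ± 13.4 (edgeR adjusted p 0.000819 each). In preCFU-E they were led by Ptbp1, Ripor2, Col4a3bp, Rps24, Agbl5, Atp6v1h and Rtn4, with Rtn4-203 at 70.7% ± 5.98 against 20.2% ± 2.48 (edgeR adjusted p 0.00434) and Atp6v1h-204 at 28.2% ± 5.86 against 0% (0.00371). In HSC Qk, Ptbp1, Aldh2, Wnk1, Immt, Fbxo9, Rnf220 and Col4a3bp led. The pyruvate kinase gene Pkm, a known PTBP1 target, did not pass (edgeR adjusted p 1 in each population): its transcript Pkm-202 held 27.1% ± 7.89 in KO against 13.4% ± 1.21 in HSC, 22.4% ± 6.54 against 8.25% ± 0.734 in preMegE and 21.2% ± 5.23 against 8.25% ± 4.25 in preCFU-E. Usage of Ptbp2 and Ptbp3 transcripts did not pass either, except in HSC for Ptbp3 without KO 3 (0.0112) and for Ptbp2 with limma's diffSplice. Single libraries ended the preMegE calls of Abi1 (KO 2; 0.0579), Ktn1 (WT 1 or WT 2; up to 1) and Mars (any WT library; up to 0.0695) and the preCFU-E calls of Atp6v1h (WT 2 or WT 3; up to 0.0562) and Rtn4 (KO 2 or KO 3; up to 0.127). With own libraries Qk, Aldh2, Immt, Fbxo9 and Rnf220 were lost in HSC (0.0782 to 1) and Ripor2, Col4a3bp and Rtn4 in preCFU-E (1 each). With a 10% share Qk, Wnk1, Rnf220 and Col4a3bp in HSC (0.168 to 1), Ktn1 in preMegE, and Col4a3bp and Atp6v1h in preCFU-E (1 each) were lost. With diffSplice Rtn4 in preMegE (0.0514) and Ripor2, Rtn4 and Rps24 in preCFU-E were lost, and without the 3 libraries that stand apart Rtn4 in preCFU-E was (0.0609). EdgeR called 408, 13 and 22 of 9364 genes in HSC, preMegE and preCFU-E. With a population's own libraries these were 25, 63 and 86, and the simulations of the shared fit gave 322, 28 and 20 false usage calls. The preMegE count was 30 without KO 3 and the preCFU-E count 13 without KO 3.

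The KO effects themselves were compared between populations. The Ptbp2 rise was larger in preCFU-E than in HSC (difference of log2 changes 2.73, SE 0.25, adjusted p 6.01e-06), a call that held in every setting and every fit without 1 library. The differences of 1.18 (SE 0.24) between preMegE and HSC and 1.56 (SE 0.25) between preCFU-E and preMegE did not pass in edgeR (adjusted p 0.121 and 0.0576), though the first passed without HSC KO 2 or KO 3 (down to 0.0427) and DESeq2 called both. Txnip, a thioredoxin inhibitor gene, was at 147 CPM in KO against 306 in WT HSC and at 501 against 419 in preMegE. Igsf3, Sdsl, Hps1, Gabbr1 and Cst3 differed as well. Igsf3 was lost without HSC WT 2 (0.0533) and Hps1 without preCFU-E KO 2 (0.0532), as was Sdsl between preCFU-E and HSC. Gabbr1 was lost without preCFU-E WT 1, WT 2, KO 1 or KO 2 (up to 0.121), and Cst3 without HSC WT 2 or WT 3 or any preCFU-E library (up to 0.195). Between preMegE and HSC, Sdsl was lost without HSC WT 2 or WT 3 or any preMegE library but KO 3 (up to 0.142) and Txnip without HSC WT 1 or WT 2 or any preMegE library but KO 1 (up to 0.153). Txnip between preCFU-E and HSC was lost without HSC WT 1, WT 2 or KO 1 or any preCFU-E library (up to 0.281). In fits of the groups compared alone Igsf3, Sdsl between preMegE and HSC, Gabbr1, Cst3 and both Txnip calls were lost (0.0609 to 0.364), with length-scaled counts Gabbr1, Hps1, Cst3 and both Txnip calls (up to 0.321), and with voom Igsf3, Cst3 and the same Sdsl call. Without the 3 libraries that stand apart Cst3 and that Sdsl call were lost. For Ptbp1 the differences from HSC were -0.69 (SE 0.18) in preMegE and -0.94 (SE 0.18) in preCFU-E, with edgeR adjusted p of 0.224 and 0.0604; the latter passed without HSC KO 1 or KO 3 (down to 0.0308) and in DESeq2. In all, edgeR called 7 genes between preMegE and HSC and 11 between preCFU-E and HSC, 4 of them processed pseudogenes in each, where simulations of these tests gave 19 or 22 and 18 false calls. The first count was 16, 18, 34 and 48 without HSC WT 1, KO 1, KO 2 and KO 3, and 4 without HSC WT 2, preMegE WT 2 or preMegE WT 3. The second was 18, 23, 22 and 47 without HSC WT 1, KO 1, KO 2 and KO 3, 7 without preCFU-E WT 1, WT 3 or KO 3, 6 without WT 2 or KO 1 and 4 without KO 2. Between preCFU-E and preMegE edgeR called 0 genes, with 564 at an unadjusted p under 0.05, where DESeq2 called 10 and voom 3.

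Among WT cells, the step from HSC to preMegE carried the ribosomal and erythroid genes upward and the stem cell genes downward. Rps2 rose from 105 ± 3.59 to 814 ± 99.2 CPM (log2 2.96, SE 0.13) and the ribosome-bound scaffold gene Rack1 from 160 ± 5.46 to 1040 ± 112 (2.70, SE 0.13). Aqp1 rose by 4.56 (SE 0.22), Tulp4 by 3.94 (SE 0.19) and Klf1, the erythroid transcription factor gene, from 0.858 ± 0.531 to 64.5 ± 4.35 CPM (6.19, SE 0.32). The stem cell transcription factor genes Hlf (614 ± 3.09 to 27.7 ± 2.49 CPM) and Mecom (183 ± 2.66 to 9.92 ± 2.23) fell, as did Fgd5, Dst, Prex2, Stxbp4 and Mmrn1. All had edgeR adjusted p between 1.2e-12 and 1.08e-09. Of the large-subunit ribosomal protein genes 45 of 47 rose and of the small-subunit genes 30 of 32, the same counts when adjusted over the list alone (camera adjusted p 1.12e-40 and 4.71e-36, and adjusted p = 0.0109 for both with an estimated correlation). Ribosome biogenesis factors (56 of 60 rose, 57 over the list alone) and translation factors (35 of 36, 36 over the list alone) had adjusted p = 0.0699 with an estimated correlation. Erythroid markers (32 of 40 rose, 3 fell, the same over the list alone; median 1.78) and the HSC signature (32 of 40 fell, 3 rose, 4 over the list alone; median -2.16) had adjusted p = 0.0319 and 0.0109 with an estimated correlation. Megakaryocyte genes went both ways: F2r rose (2.79, SE 0.19) while Selp (-3.90, SE 0.36) fell, and 12 of 13 tested mitochondrially encoded genes fell, also over the list alone (adjusted p = 0.226 with an estimated correlation). Ptbp1 rose (1.73, SE 0.13), Ptbp3 rose (1.41, SE 0.14) and Ptbp2 fell (-1.65, SE 0.18). EdgeR called 11571 genes, 5491 higher and 6080 lower, and the median of all genes was -0.43 with TMM, -0.50 with RLE and -0.33 with length-scaled counts, and the named genes kept their directions under each. The difference of sex genes between these libraries goes with every one of these changes.

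From WT preMegE to WT preCFU-E, where the sex genes matched, the erythroid program rose further and megakaryocyte and stem cell genes fell. The spectrin-binding genes Add2 (9.74 ± 0.781 to 109 ± 17.2 CPM; log2 3.48, SE 0.20) and Ank1 (28.3 ± 2.5 to 245 ± 21.1; 3.12, SE 0.25) rose, with Minpp1 (2.51, SE 0.15), the transcription factor gene Nfia (2.89, SE 0.17), Spire1 (3.41, SE 0.21) and the asparagine synthetase gene Asns (3.86, SE 0.25). Meis1 fell from 168 ± 11 to 7.49 ± 1.53 CPM (-4.48, SE 0.17) and Itga2b from 82.9 ± 9.9 to 2 ± 0.3 (-5.37, SE 0.36), with Adgrl4, Sptan1, Mycn and Tie1. Of 25 megakaryocyte markers 20 fell and 0 rose (camera adjusted p 1.6e-32; adjusted p = 0.00254 with an estimated correlation), counts that were the same over the list alone. Of 40 HSC signature genes 32 fell and 1 rose (35 and 1 over the list alone; adjusted p = 0.000188 with an estimated correlation), and of 40 erythroid markers 29 rose and 1 fell (33 and 1; adjusted p = 0.00689). Of the large- and small-subunit ribosomal protein genes 37 of 47 and 22 of 32 rose (41 and 27 over the list alone), with medians of 0.51 and 0.44, and adjusted p = 0.0977 and 0.172 with an estimated correlation. Rpl14 rose by 0.71 (SE 0.11), Rpl41 by 1.00 (SE 0.16), Rps2 by 0.80 (SE 0.12) and Rps23 by 0.61 (SE 0.11). Ptbp1 rose (0.84, SE 0.13, adjusted p 3.03e-05) and Ptbp2 fell (-0.81, SE 0.18, adjusted p 0.0014), while Ptbp3 was at -0.18 (adjusted p 0.352), a fall that passed with voom, the stricter filter, protein-coding genes alone (0.0254) and these libraries alone (0.0295). EdgeR called 5779 genes, 3364 higher and 2415 lower.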

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

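The tests chosen only after the result was seen were those of the shared spread and of single libraries for the HSC count, of RNA from more mature cells for the pseudogenes, and those of explanations for the Ptbp2 rise, whose differences between populations were planned tests.

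HSC had the most called genes, 182, when all libraries were fitted together. The median absolute log2 change over genes was 0.189, and the highest of the 9 other splits of the 6 HSC libraries gave 0.192, so a larger effect of the genotype in HSC cannot be told apart from the spread of its libraries. KO 2, the library that stands apart, is argued against as the source of the count, since 222 genes were called without it, but other single libraries moved it, to 89 without WT 2, 395 without KO 1 and 595 without KO 3. From the HSC libraries alone 5 genes were called, where preCFU-E libraries alone gave 252. A spread estimated jointly with the less variable progenitors may account for part or most of the HSC count. The shared fit gave 156 false calls in simulation. The fit of HSC libraries alone also recovered fewer simulated log2 changes of 1 and 2, 8% and 49% against 35% and 69%. In the 9 other splits of the HSC libraries the shared fit called 3 to 46 genes, so the size of that part stays open. What a larger HSC experiment would call stays open.

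Processed pseudogenes listed at 0 reads in all HSC WT libraries had reads in all HSC KO libraries. Rps23-ps1 had 64 to 186 reads in HSC KO, Gm10163 146 to 267, Gm15429 14 to 59 and Gm5616 14 to 47, with differences of log2 change of -9.64, -10.39, -7.79 and -7.48 between preMegE and HSC and of -9.76, -10.77, -7.61 and -7.27 between preCFU-E and HSC. These fitted folds depend on the prior count and are no bounds. RNA of more mature cells is argued against: 8 genes abundant in preMegE WT and near 0 in HSC WT reached a median of 0% of their preMegE level in HSC KO, where the pseudogenes reached 2.59% to 66.1%. Assignment of shared reads to different near-identical copies from library to library may account for the pattern: other splits of the HSC libraries gave up to 3 such pseudogenes against 6 in the labelled split, and a genotype effect on these copies stays untested.

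The rise of Ptbp2 had log2 changes of 1.04, 2.22 and 3.78 in HSC, preMegE and preCFU-E, and of the differences only that between preCFU-E and HSC passed in edgeR (preMegE against HSC had an adjusted p of 0.121). Cells that kept Ptbp1 are argued against as the whole cause: 71% (SE 9.18) and 91.7% (SE 2.71) of HSC KO cells would have to have kept it to lower the rises of preMegE and preCFU-E to that of HSC, where 47.1% (SE 2.92) of WT Ptbp1 CPM and 3.29% of its protein-coding TPM were left. Between preCFU-E and preMegE, whose rises differed by 1.56 (SE 0.25, edgeR adjusted p 0.0576), different WT levels that reach a like level in KO are argued against, as Ptbp2 in preCFU-E stood at 0.74 (SE 0.09) on the log2 scale relative to preMegE among KO libraries and at -0.82 (SE 0.20) among WT. This stays a candidate explanation for preCFU-E against HSC (0.27, SE 0.16, in KO and -2.48, SE 0.24, in WT) and is open for preMegE against HSC (-0.48, SE 0.17, and -1.66, SE 0.19). Sex and library differences of the HSC samples cannot be told apart from cell type in comparisons with HSC (1.18 for preMegE), as all HSC libraries differ in the sex genes.

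The remaining results are genes whose KO effect differed between populations by edgeR's test of the difference. Ptbp2 differed by 2.73 between preCFU-E and HSC. Igsf3 differed by -2.28 between preMegE and HSC, at 3.75 CPM in WT and 8.47 in KO HSC and 15 and 6.98 in preMegE. Txnip differed by 1.31 between preMegE and HSC and by 1.20 between preCFU-E and HSC. Sdsl differed by -2.11 and -2.37 in the same order, at 5.65 and 15.9 CPM in WT and KO HSC, 25.4 and 16.4 in preMegE and 26 and 14.1 in preCFU-E. Hps1 differed by -2.22 between preCFU-E and HSC, at 15.6 and 32.2 CPM in HSC and 14.2 and 6.33 in preCFU-E. Gabbr1 differed by 2.72, at 61 and 66.6 CPM in HSC and 0.277 and 1.92 in preCFU-E. Cst3 differed by 1.14, at 32.6 and 18.7 CPM in HSC and 43.1 and 54.6 in preCFU-E. Add2 differed by 5.18, a fitted value that is no bound, since HSC KO libraries had 0 reads. Comparisons with HSC use the same HSC libraries and so share their chance values.

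Other splits of the same libraries were fitted in the same way. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The number of splits with a result as large, the labelled one included, was 1 for the genes called in HSC (182, highest other 46), preMegE (13, highest other 0) and preCFU-E (33, highest other 0), and 1 for WT preMegE against HSC (11571, highest other 0) and WT preCFU-E against preMegE (5779, highest other 0). For gene lists it was 7 in HSC (4 lists, highest other 9), 4 in preMegE (16, highest other 18) and 5 in preCFU-E (15, highest other 24). For transcript usage it was 1 in HSC (408, highest other 374), 2 in preMegE (13, highest other 14) and 1 in preCFU-E (22, highest other 8). For cassette exons it was 1 in each, with 114, 13 and 31 exons and 75, 2 and 5 in the highest other split. Of 100 splits drawn for differences between populations, 1 gave as many genes for preMegE against HSC (7, highest other 6) and 1 for preCFU-E against HSC (11, highest other 6), while 100 did for preCFU-E against preMegE (0, highest other 28). For both comparisons with HSC the labelled grouping gave more genes than any other of the 100, but only 7 against 6 in the first. Both counts rest on the same HSC libraries. Simulations of these tests gave 19 or 22 and 18 false calls, more than were called, so chance is not excluded for either count. The 28 genes came from a single split, the others giving at most 2; so many against 0 point to a structure of those samples, which was not tested.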

How the results depend on the processing

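The tests chosen after the data were seen are the fits without mitochondrial ribosomal RNA genes, those of lists, usage, exons and overlaps on a population's own libraries, and those without 3 libraries that stand apart. Numbers are given for HSC, preMegE and preCFU-E in that order unless named, and the cause of a moved number was not tested except where stated. RLE factors, protein-coding genes alone and leaving out mitochondrial ribosomal RNA genes kept all gene counts within 1.5 times.

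With DESeq2 the gene counts were 647, 59 and 77, and the differences preMegE against HSC, preCFU-E against HSC and preCFU-E against preMegE gave 131, 122 and 10. Voom gave 7, 258 and 368 genes, 3 for preMegE against HSC, 3 for preCFU-E against preMegE and 10610 for WT preCFU-E against preMegE. No filter gave 360, 27 and 54, and 41, 35 and 4 for the differences. The stricter filter gave 7185 for WT preMegE against HSC, where fewer genes were tested. Length-scaled counts gave 7 in preMegE, 15 in preCFU-E and 7 for preCFU-E against HSC. Fits of the groups compared alone gave 5, 36 and 252, and 2, 6 and 1 for the differences. Without the 3 libraries that stand apart, preMegE gave 21 genes and the differences from HSC 17 and 19.

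For lists, the estimated correlation and fry each left 0, 0 and 0, against 4, 16 and 15 with camera. Usage gave 860, 80 and 73 with limma's diffSplice, 251 in HSC and 14 in preCFU-E at a 10% share, 25, 63 and 86 with own libraries and 29 in preMegE without the 3 libraries. Exons gave 60 in HSC at 20 TPM, and 4 in HSC and 70 in preCFU-E with own libraries. Shared genes were 4 for HSC and preMegE (2 at p under 0.01, 17 with DESeq2, 2 with own libraries), 8 for HSC and preCFU-E (4, 19 and 2) and 9 for preMegE and preCFU-E (26 with DESeq2, 23 with own libraries).

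Whether replicate numbers pair the samples is not given in the labels, and correlations among 3 libraries per group cannot settle it. Same-numbered WT and KO libraries correlated at -0.0044, -0.0015 and 0.00093 in HSC, 0.14, 0.012 and 0.086 in preMegE and 0.0084, -0.038 and 0.024 in preCFU-E. They correlated best with their own number in 0, 2 and 1 of 3. WT preMegE and preCFU-E did so in 3 of 3 (0.24, 0.076 and 0.18), as did KO preMegE and preCFU-E (0.017, 0.047 and 0.046), a hint from the data. With the replicate block the counts moved to 94 genes in HSC, 4 for preMegE against HSC, 156 usage genes in HSC and 11 in preCFU-E, and 75, 5 and 10 exons. Of named calls 20 of genes, 6 of usage and 14 of exons did not pass with it, among them Pde3b, B4galt6, Tmem86b and Pgm2 and the exons of Anxa7, Arih1, Rps24, Mars, Reep6 and Tmem184b in preMegE and of Ptbp2, Ptbp1 (78 nt), Arih1, Rps24, Mars and Tmem184b in preCFU-E.

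Leaving out each library in turn gave 89 to 595, 4 to 9 and 14 to 27 genes, 4 to 48, 4 to 47 and 0 to 0 for the differences, 8991 to 10580 and 3969 to 5058 for the WT comparisons, 3 to 6, 14 to 21 and 7 to 15 lists, 332 to 474, 10 to 30 and 13 to 22 usage genes, and 128 to 228, 4 to 13 and 11 to 29 exons. The preCFU-E list count was 7 without preCFU-E KO 2. The adjusted p of list translation factors, KO vs WT, preCFU-E, ran from 0.00214 to 0.756 over these fits, and the list turned down without WT 1 (0.756). That of list ribosomal proteins, small subunit, KO vs WT, preCFU-E, ran from 0.000454 to 0.624, and the list turned down without WT 3 (0.5). Depth was 15956408 to 29226287 reads per library, and genes with few reads, such as Add2 in HSC, are limited by it.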

Other observations

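The Fisher tests of this part were planned before their results were seen, while the Rps24 exon in preCFU-E and the lists described were chosen after their values were seen.

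Other lists moved between the WT populations. From HSC to preMegE, nuclear genes of oxidative phosphorylation rose in 51 of 61 members (also 51 adjusted over the list alone; median 1.35, adjusted p = 0.0319 with an estimated correlation), and heme and iron genes in 23 of 31 with 4 lower (the same over the list alone; median 1.24, adjusted p = 0.0319 with an estimated correlation). From preMegE to preCFU-E the same lists rose in 57 of 61 members (60 adjusted over the list alone) and 24 of 31 (27 over the list alone, with 1 lower), with medians of 1.05 and 1.02 and adjusted p = 0.00689 with an estimated correlation for each. Mitochondrial ribosomal protein genes rose in 58 of 74 (64 over the list alone; median 0.96, adjusted p = 0.00877 with an estimated correlation). Immediate early genes fell in 8 of 20 with 1 higher, the same counts over the list alone, with a median of -1.74 (adjusted p = 0.022 with an estimated correlation).

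The 20-nt exon of Rps24 had values that differed between populations as well as between genotypes. They compare Rps24-202 and Rps24-207 with Rps24-210, a small part of the gene's transcripts in preCFU-E, where Rps24-201, outside the comparison, held 93.4% of the TPM in KO and 94.6% in WT. It was spliced in at 96.8%, 96.1% and 96% in the WT HSC libraries, 57.6%, 50.6% and 60.2% in WT preMegE and 6.56%, 6.7% and 8.38% in WT preCFU-E. KO libraries had 97.9%, 96.3% and 96.2% in HSC, 85.8%, 89.2% and 90.4% in preMegE and 27.7%, 25.7% and 22.7% in preCFU-E. The KO change was called in preMegE and preCFU-E (limma adjusted p 0.0085 and 0.0241). It was lost without WT 1, WT 2 or KO 2 in preMegE (up to 0.0627) and without any 1 library in preCFU-E (up to 0.143), and the WT differences between populations were not tested.

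It was a hypothesis that genes that fell in KO may be those whose transcripts were remodelled. In preMegE 0 of 3 genes that fell, Ptbp1 left out, had an unadjusted usage p under 0.05, against 4.75% of 9354 uncalled genes (one-sided Fisher exact p 1). In preCFU-E 2 of 14 did, Uvssa and Clca3a1, against 3.56% of 9337 (one-sided Fisher exact p 0.0873). With so few genes the question stays open.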
